A study of Rattus norvegicus with 4 samples.

How the data were processed

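Total RNA came from 4 cultures of NR8383 cells exposed to NM403, labelled as 4 biological replicates, and was hybridised to 1-colour (Cy3) Agilent rat arrays. Per the labels' protocols, cells were seeded for 48 h in 25 cm² flasks in medium with 15% serum, RNA had an integrity number above 7.5, and 100 ng was labelled. Per the labels the cells had gone through 20 passages. The deposited files hold the scanner intensity of each spot, made with Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes. Per the file headers, the processed intensity is background-subtracted and detrended within each array, with no normalization between arrays, and the array design names the rat build rn4. The other deposited columns used were the median intensity of the spot and of its local background, and flags set by the software. Per the file headers, Feature Extraction found its quality measures in range on replicates 1, 2 and 3 and marked replicate 4 for evaluation, with 2 measures out of range.

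Control spots and spots flagged as non-uniform or population outliers were left out (623 to 1016 outlier spots per array), and no spot was saturated. Spots of a probe were averaged on the log2 scale. Of 45598 non-control probes, 43279 were printed 1 time, 969 were printed 2 times and 1350 were printed 10 times per array. Gene names came from the probes' accessions, matched without version to the RefSeq gene table of rat assembly GRCr8. The build of that table differs from that of the array, so no coordinates are given. In all, 21109 probes (46.3%) matched 1 gene symbol, 0 matched several and 24489 matched none; the unmatched ones include 6958 with an Ensembl transcript name. Unmatched probes entered no value of a gene or gene list, but they took part in the scaling, in the comparisons of spots and repeated probes, and in the correlation over all non-control probes. A probe was detected on an array where Feature Extraction called it well above background, for repeated probes where more than 50% of its spots were. A gene was detected where any of its probes was, and took the level of its brightest probe. Eligible genes had that probe detected on all 4 arrays.

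Because 34.2% of the non-control probes were detected on all arrays, below the 50% set in advance for this choice, each array was scaled by subtracting the 75th percentile of the log2 processed intensity of those detected probes. Scaling on a percentile sets this value alike on all arrays and hides any change in total messenger RNA. There was 1 group, so no contrast, fold change or test between groups was computed. The 4 arrays analysed here lay on 1 slide, so slides could not be compared. Other batches, such as RNA extraction or labelling, were not examined. Gene lists, list tests, thresholds and the rule for named genes were chosen before the data were examined. For spread, the median SD of each list was set against 10000 random lists of like size matched in 20 level bins (two-sided). For a joint shift, the SD over arrays of the list's mean deviation was set against 10000 random lists matched in 10 level bins by 3 SD bins (one-sided). The p-values were adjusted by the Benjamini-Hochberg method over the lists with at least 5 eligible members. The named genes were 47 fixed genes, the 15 eligible genes with the largest SD above the median level, the 4 members with the largest SD of each list past a test, and up to 4 members of each other-cell marker list detected on all arrays. Of the 47 fixed genes, 33 were detected on all arrays, 2 on some, 9 on none and 3 had no named probe. Other list members given as examples were chosen after their values were seen.

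The list tests were tested on simulated data, with known changes added to random lists of 20 genes among the 7937 eligible genes and 1000 random lists each. With nothing added, 1 of 200 lists was called for a shift and 0 for spread. A joint shift with an SD of 0.4 was called in 25 of 25 lists, of 0.2 in 15 of 25 and of 0.1 in 0 of 25. A spread 3 times as wide was called in 25 of 25 lists, 2 times as wide in 21 of 25 and 1.5 times as wide in 9 of 25. All 25 lists of a run were changed together and adjusted over those 25. These shares therefore do not hold for 1 changed list among unchanged ones, where the adjustment is stricter.

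Alternatives were other detection rules, leaving out each replicate in turn, normexp background correction with an offset of 50, quantile normalization, scaling on the array median or on all non-control probes, the mean over a gene's probes, other filters on dim genes and other matching of random lists. Normexp was run on the median spot intensity in place of the mean spot intensity that had been planned, which was not used here. Local bright patches were searched for after the data were seen: a spot was raised where its signal, floored at 50, was at least 4-fold over the median of the other arrays, and its neighbours were the spots within 2 rows and 2 columns, with those within 6 rows in the same column counted too. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.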

Results

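NR8383 is a rat alveolar macrophage line that was started from lung lavage cells. The study exposed NR8383 cultures to NM403, a multi-walled carbon nanotube, at 0.8 cm² of material per cm² of culture for 4 h and measured messenger RNA on 1-colour Agilent arrays. The 4 arrays analysed here form 1 group of 4 biological replicates, all exposed. The design text also names unexposed cultures, which were not analysed here, so no gene could be tested for a response to NM403. The question that remained open to these arrays was which transcripts the exposed cells contained and how far the 4 cultures differed in them. All 4 arrays lay on 1 slide and were scanned in 1 session. Any other arrays of that slide were not analysed here. Each array held 62976 spots, 58717 of which were not controls. The share of those spots well above background was 50.8% on replicate 1, 47.5% on replicate 2, 49.6% on replicate 3 and 45.9% on replicate 4. The number of arrays limits the precision of every value below.

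The exposed cells contained transcripts of most macrophage, stress and housekeeping genes on the lists. Of 16581 genes with a named probe, 7944 (47.9%) were detected on all 4 arrays, 1931 on 1 to 3 arrays and 6706 on none. The number of named genes detected per array ran from 8387 on replicate 4 to 9028 on replicate 1. Background was measured with 308 negative control spots per array. Between 7 and 11 of them were called well above background, a share of 2.27% (95% exact interval 0.919 to 4.63) on replicate 1 and 3.57% (1.80 to 6.30) on replicate 3, the lowest and highest of the 4 arrays. These intervals take the spots of 1 array as independent, and would be too narrow if the spots are not. Levels below are log2 signals relative to the 75th percentile of the probes detected on all arrays of the same array, as mean ± SD over the 4 cultures (n = 4 for every level). They describe 1 probe across cultures and do not rank genes against each other. The lowest levels given, such as those of Msr1 on replicates 2 and 4 (-5.31 and -5.33), lie close to where probes stop being called. An Ebf1 probe that read between -5.86 and -5.63 was above background on 1 array alone. The SDs depend on the scaling: of the 71 named genes, 43 had an SD that moved by over 1.5 times with the percentile over all non-control probes, 36 with the array median and 34 with quantile normalization.

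Macrophage identity genes were detected widely, with named gaps. Of 29 measured members of this list, 22 were detected on all 4 arrays. Cd68, a lysosomal membrane glycoprotein of macrophages, had a level of 3.76 ± 0.25. Mrc1, the mannose receptor, had a level of -1.48 ± 0.08, and Itgam, the alpha subunit of complement receptor 3, of -1.35 ± 0.17, with an SD of 0.0861 without replicate 2. The scavenger receptor gene Msr1 had a level of -4.63 ± 0.80 and a 2.64-fold range between the highest and lowest culture. Marco, another scavenger receptor, and Adgre1, which encodes the F4/80 antigen, were not well above background on any array. The complement genes C1qa, C1qb and C1qc and the transcription factor gene Cebpa were also not well above background on any array. Of 22 measured scavenger receptor and phagocytosis genes, 17 were detected on all arrays. Lysosomal genes were detected for 31 of 32 members, among them Lamp1 at 2.61 ± 0.09, with an SD of 0.0594 without replicate 1, and the protease gene Ctsd at 5.62 ± 0.20. Antigen presentation genes were detected for 12 of 20 members. The class I genes B2m and RT1-A1 were among them, while Cd74, Ciita, Cd40 and Cd86 were not well above background on any array.

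Inflammatory mediators were present in part. Of 32 measured cytokine and chemokine genes, 17 were detected on all 4 arrays, 3 on 1 to 3 arrays and 12 on none. Tnf had a level of 2.14 ± 0.18, Il1b of 2.63 ± 0.08 and Il1a of 0.66 ± 0.35. A second Tnf probe, also detected on all 4 arrays, read between -3.30 and -3.04. Among the chemokines that attract monocytes and other leukocytes, Ccl2 had a level of 2.49 ± 0.06, Ccl3 of 4.23 ± 0.15 and Ccl4 of 1.64 ± 0.25. Cxcl2, a neutrophil attractant, had a level of -1.53 ± 0.12. Without replicate 2 the SD of Il1b was 0.0143 and that of Ccl2 0.00979, and without replicate 3 that of Cxcl2 was 0.0625. Il6, Il10 and Cxcl1 were not well above background on any array, and neither was Ptgs2, the inducible prostaglandin synthase. Ccl20 was above background on 2 arrays. Nos2, the inducible nitric oxide synthase, was above background on 3 arrays. Its brighter probe read 4.58 on replicate 4 and between -6.90 and -4.70 on the others, and 7 of the 24 spots around it on replicate 4 were raised at least 4-fold over the other arrays, so that reading is not taken as a transcript level. The second Nos2 probe lay elsewhere on the array, had 0 raised neighbours and read -5.05 on replicate 4, where it was above background, and between -7.41 and -7.18 on the others. Arg1, which encodes the arginase that uses the same substrate, had a level of 0.18 ± 0.16.

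Inflammasome genes were detected for 12 of 15 measured members. Nlrp3, the sensor, had a level of -2.46 ± 0.23, with an SD of 0.114 without replicate 1, and Casp1, the protease that processes interleukin 1 beta, of -1.29 ± 0.22. Il18 had a level of 1.05 ± 0.08. NF-kB pathway and feedback genes were detected for 19 of 20 members. The inhibitor gene Nfkbia had a level of 0.56 ± 0.38, and the adhesion molecule gene Icam1 of 1.49 ± 0.24. Tnfaip3 had no named probe. Of 27 interferon response genes, 23 were detected on all arrays, and of 30 immediate early genes, 19. Atf3, a stress-induced transcription factor that is also on the immediate early list, had a level of 0.04 ± 0.14.

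Antioxidant and stress genes were nearly all detected. Of 24 measured NRF2 antioxidant genes, 22 were detected on all 4 arrays. Hmox1, the inducible heme oxygenase, had a level of 4.51 ± 0.17, Srxn1 of 3.22 ± 0.25, Txnrd1 of -0.75 ± 0.24, Nqo1 of -1.84 ± 0.19 and Sod2 of 0.79 ± 0.26. The SD of Hmox1 was 0.0852 without replicate 2. Gclm, a subunit of the glutathione-synthesis enzyme, was not well above background on any array, whereas its partner Gclc was detected on all. Slc7a11, the cystine transporter, read 1.76, 0.00, 1.69 and 0.11 on replicates 1 to 4, a 3.38-fold range. Heat shock genes were detected for 12 of 14 members, and Hspa1b had no named probe. Unfolded protein and integrated stress response genes were detected for 23 of 24 members. Ddit3, the CHOP transcription factor, had a level of 1.61 ± 0.49, and its SD was 0.0896 without replicate 4, which read 0.89 against 1.73 to 1.91 on the others. Metal handling genes were detected for 14 of 16 members.

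Damage response and cell cycle genes were detected as follows. Of 21 measured p53 and DNA damage response genes, 16 were detected on all arrays. Cdkn1a, the p21 cell cycle inhibitor, had a level of 2.20 ± 0.29, Mdm2 of -1.08 ± 0.12 and Gadd45a of 0.17 ± 0.41. A second Cdkn1a probe, also detected on all 4 arrays, read between -4.19 and -3.20. Detection on all arrays held for 22 of 26 DNA repair genes, 21 of 22 S phase genes, 23 of 24 mitosis genes and 25 of 27 apoptosis genes. Mki67, a proliferation marker, read 1.03, -0.53, 1.11 and -0.47 on replicates 1 to 4, a 3.11-fold range. Its 4 probes were all detected on every array, with SDs from 0.91 to 0.97. Top2a had no named probe. Matrix remodelling and fibrosis mediators were detected for 12 of 29 members. Mmp9 had a level of -3.17 ± 0.27 and the macrophage elastase gene Mmp12 of -2.85 ± 0.22, while Timp1 and Spp1 were not well above background on any array.

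All 30 measured oxidative phosphorylation genes, all 31 ribosomal protein genes and all 26 proteasome genes were detected on all 4 arrays. Detection held for 26 of 27 cholesterol synthesis and efflux genes, 31 of 32 cytoskeleton and adhesion genes, 21 of 25 glycolysis and hypoxia genes and 19 of 23 autophagy genes.

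Most markers of other cell types were not detected on all arrays. On all 4 arrays, detection held for 1 of 19 alveolar and airway epithelial markers, 1 of 16 fibroblast and smooth muscle markers, 2 of 13 neutrophil markers, 2 of 10 B cell markers and 2 of 23 liver, muscle and neuron markers. It held for 0 of 13 mast cell, basophil and eosinophil markers, 3 of 13 endothelial markers, 4 of 10 dendritic cell markers, 4 of 10 erythroid markers and 7 of 20 T cell and NK cell markers. The epithelial marker was Foxj1, at -3.85 ± 0.34, and the fibroblast marker was Dcn, at -1.88 ± 0.22. The neutrophil granule genes Camp and Lcn2 had levels of -2.45 ± 0.35 and -2.24 ± 0.40. The B cell transcription factor genes Pax5 and Ebf1 had levels of -3.38 ± 0.33 and -3.40 ± 0.46, and the SD of Pax5 was 0.205 without replicate 1. Among T cell markers, Cd3d had a level of -3.97 ± 0.17 and Lck of -4.09 ± 0.73, and the SDs were 0.0934 for Cd3d without replicate 3 and 0.28 for Lck without replicate 2. The levels of Cd28 and Il7r were -1.48 ± 0.30 and -1.34 ± 0.60. The remaining detected members of this list were Tbx21, the T-bet transcription factor gene, at 3.09 ± 0.28, Nkg7 at -3.10 ± 0.65 and Gzmb, which encodes granzyme B, at -4.97 ± 0.30. Their SDs were 0.175 for Tbx21 without replicate 1, 0.264 for Nkg7 without replicate 4 and 0.107 for Gzmb without replicate 2. Of the dendritic cell markers, Clec9a had a level of -4.89 ± 0.42, Irf4 of -2.10 ± 0.23, Batf3 of -2.96 ± 0.27 and Itgae of -3.79 ± 0.93, with an SD of 0.34 without replicate 4. The endothelial genes were Pecam1 at -2.10 ± 0.12, Cdh5 at -5.17 ± 0.33 and Vwf, which encodes von Willebrand factor, at 0.76 ± 0.47. A second Vwf probe, also detected on all 4 arrays, read between -4.96 and -4.37. The erythroid genes were Hba-a1 at -2.19 ± 0.11, Epor at -3.26 ± 0.65, Klf1 at -4.86 ± 0.58 and Tfr2 at -3.69 ± 0.22. Of the liver, muscle and neuron list, Mb had a level of -3.18 ± 0.44 and Mbp of -3.38 ± 0.04. The SDs were 0.0623 for Pecam1 and 0.00891 for Mbp without replicate 3, and 0.156 for Cdh5 and 0.0709 for Hba-a1 without replicate 1. Foxj1, Cd28, Clec9a, Irf4 and Tfr2 each had another probe that was not well above background on any array.

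**Figure D1:**
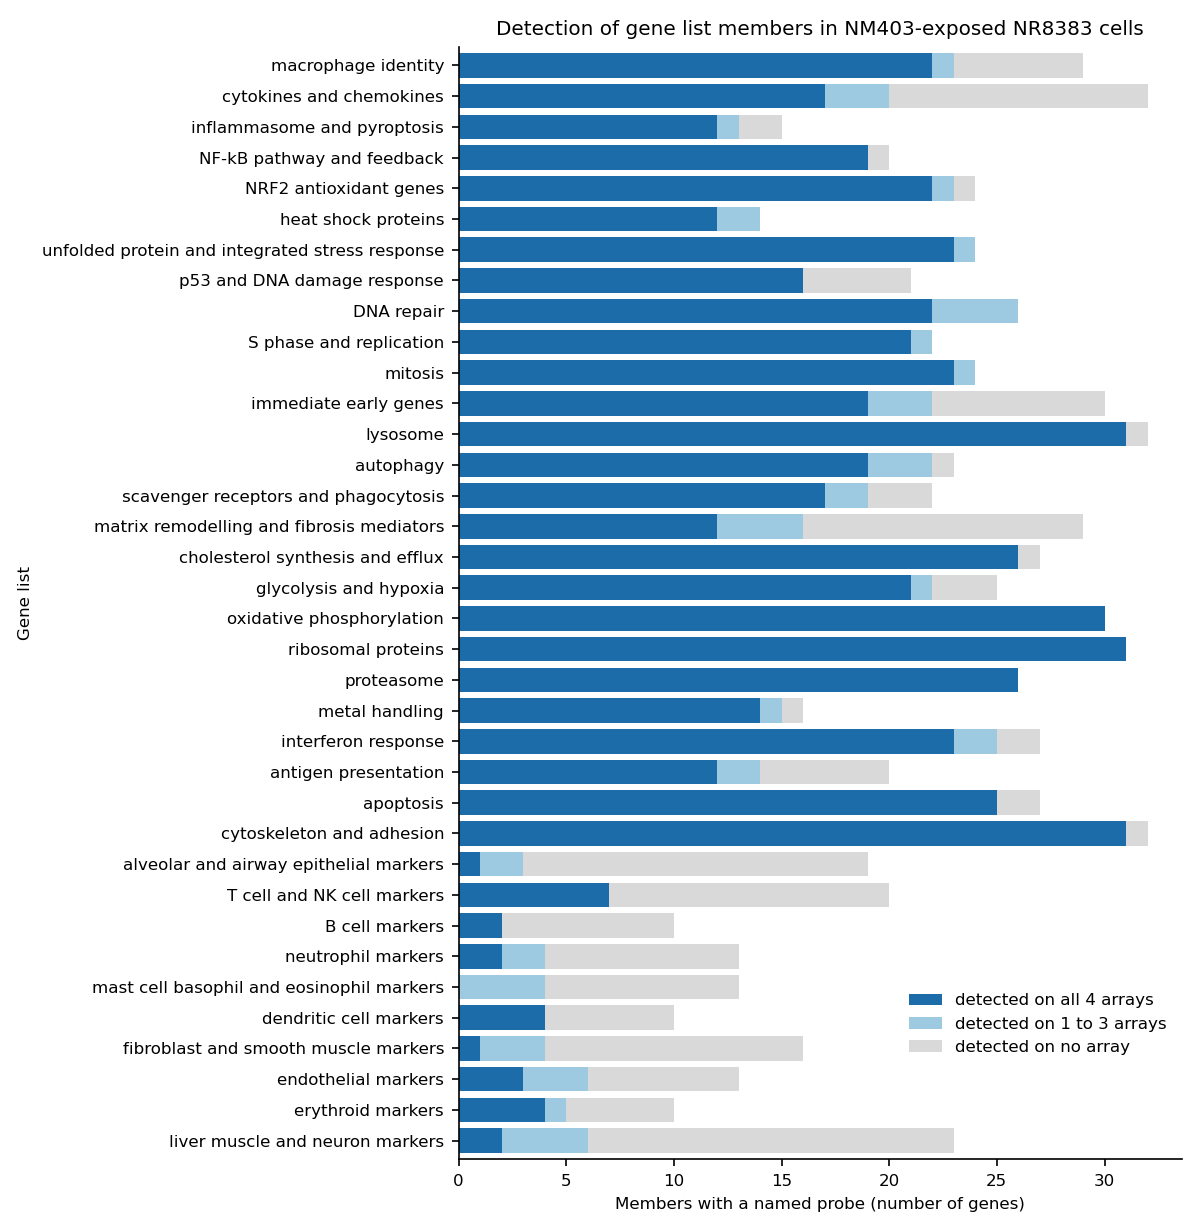
Each bar is 1 of 36 gene lists, and its length is the number of members with a named probe; colours split it into members detected on all 4 arrays, on 1 to 3 arrays and on none. Ribosomal protein genes were detected for 31 of 31 members, cytokine and chemokine genes for 17 of 32, and alveolar and airway epithelial markers for 1 of 19.

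The 4 cultures did not differ evenly. The Pearson correlation across the 7937 eligible genes was 0.996 between replicates 1 and 3 and 0.992 between replicates 2 and 4, and lay between 0.967 and 0.970 for the other 4 pairs. Genes are not independent replicates, so these correlations carry no p-value. Between replicates 1 and 3, 52 genes differed more than 2-fold, and between replicates 2 and 4, 103 genes; in the other 4 pairs 697 to 782 genes did. No spot had the same value on any pair of arrays. Over 1008 probes printed at least 3 times per array, 30.5% differed by more than 3 standard errors of the spots between replicates 1 and 3 and 41.2% between replicates 2 and 4, against 83.1% to 86.1% in the other pairs. The standard error of the spots covers noise within an array only, so these shares do not show whether the arrays of a pair came from separate cultures, and n = 4 rests on the labels, which give 4 biological replicates. The SDs given above describe arrays that fell into pairs and not an even scatter. Replicates 1 and 3 also read alike for Slc7a11, Msr1 and Mki67, as did replicates 2 and 4.

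The median between-array SD was 0.234 on the log2 scale, and the 10th and 90th percentiles over genes were 0.0806 and 0.577. Spots of the repeated probes had a median SD of 0.0476 within an array. The same probes had a median SD of 0.240 between arrays, 5.06 times as large. The median gene had a 1.40-fold range between its highest and lowest culture, and 1079 genes (13.6%) had a range above 2-fold. Of the 33 measured genes fixed in advance, 4 had a range above 2-fold: Slc7a11, Ddit3, Msr1 and Mki67. Scaling on all non-control probes raised the median SD to 0.353.

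**Figure D2:**
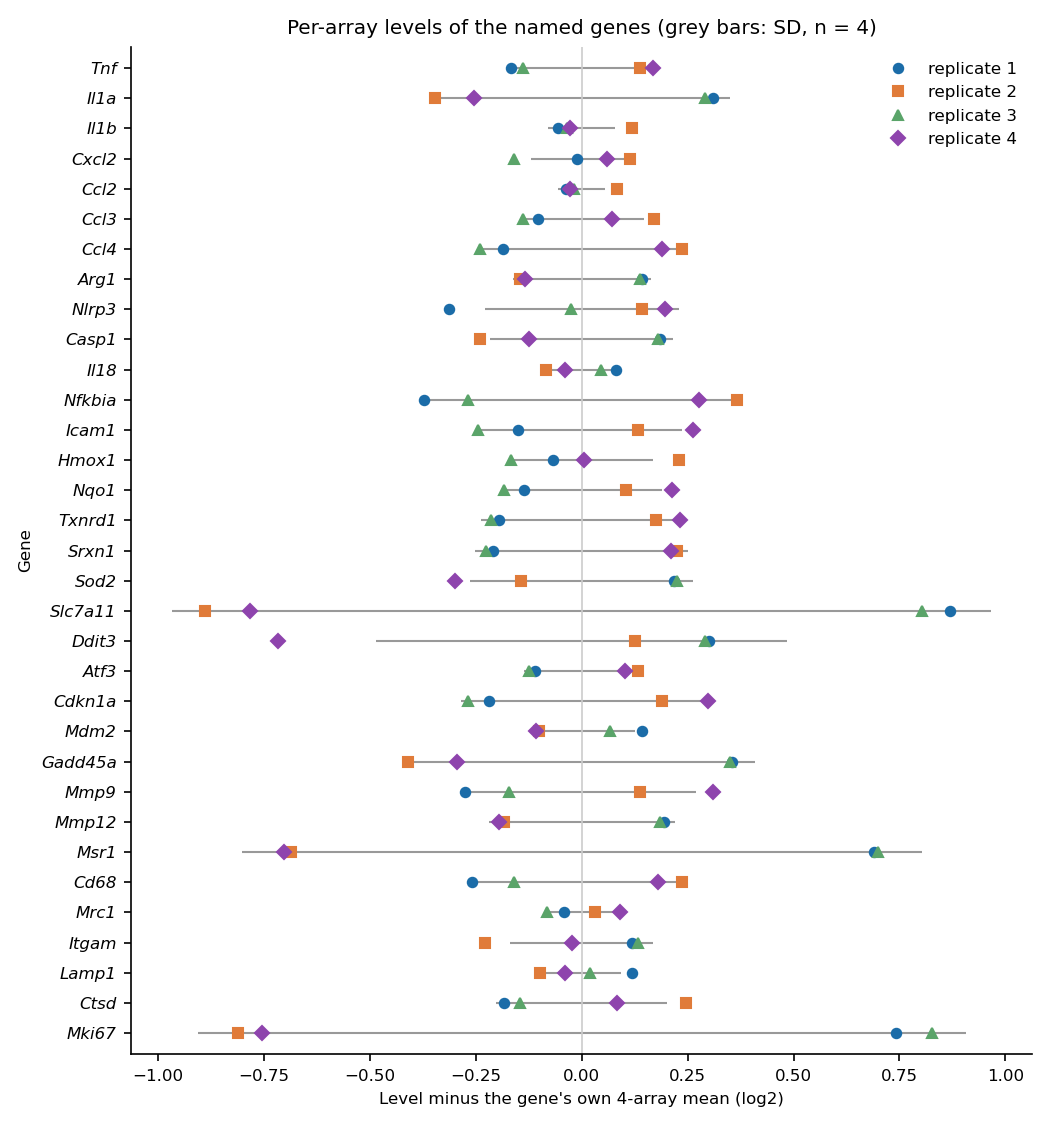
Each row is a gene fixed in advance and detected on all 4 arrays; points are the 4 cultures, placed by their log2 level minus the gene's own mean, and grey bars are the SD (n = 4). Slc7a11, Msr1 and Mki67 have the widest spread, with SDs of 0.97, 0.80 and 0.91, and Ccl2 the narrowest, with 0.06.

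No gene list passed a test of unusual spread or of a joint shift between cultures. Of the 27 lists with at least 5 eligible members, 0 passed either permutation test at an adjusted p of 0.05; without adjustment 1 list was under 0.05 for its spread and 2 for a joint shift. The S phase and replication list had the smallest p for a joint shift (one-sided permutation p = 0.0061, adjusted p = 0.165, 21 genes). Its mean deviation was -0.13 on replicate 1, 0.18 on replicate 2, -0.19 on replicate 3 and 0.14 on replicate 4. With the median in place of the mean over members its adjusted permutation p was 0.0054, and over all alternatives tried it ran from 0.0054 to 0.674. Antigen presentation genes deviated by -0.20, 0.18, -0.18 and 0.20 on replicates 1 to 4 (permutation p = 0.0477, adjusted p = 0.644, 12 genes). Glycolysis and hypoxia genes had a median SD of 0.323 against 0.225 in random lists (two-sided permutation p = 0.0254, adjusted p = 0.686, 21 genes). The response lists gave adjusted permutation p-values for a joint shift of 0.814 for cytokines and chemokines, 0.682 for the inflammasome, 0.814 for NF-kB, 0.973 for NRF2, 0.999 for heat shock and 0.814 for p53. The mean deviation of macrophage identity genes was at most 0.02 on any array (adjusted permutation p = 0.999, 22 genes), with members that went both ways. Among them Ptprc, the CD45 antigen, read 2.16, 0.77, 2.11 and 0.81 on replicates 1 to 4, and Fcgr3a, an Fc receptor gene, read 2.07, 2.62, 1.99 and 2.52. These p-values are over random gene lists and not over cultures.

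**Figure D3:**
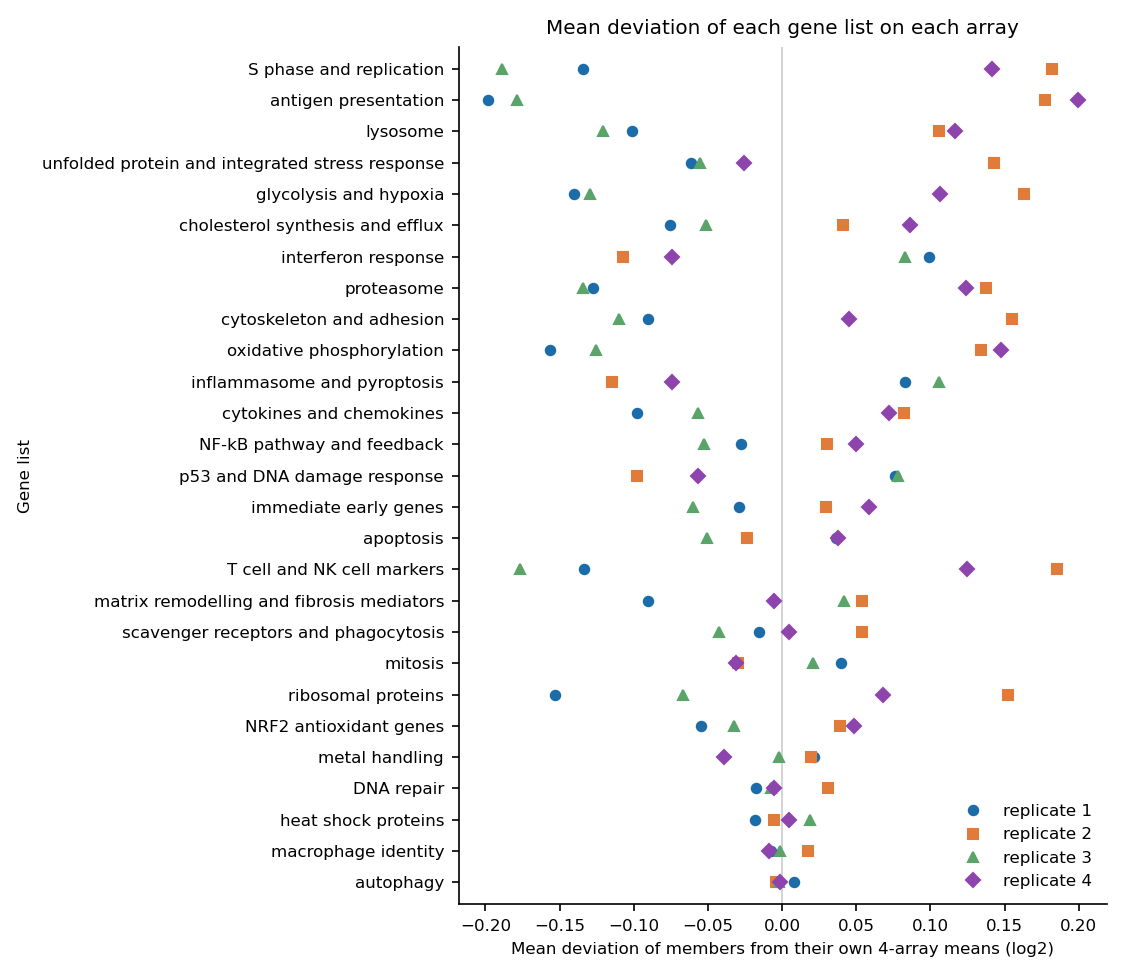
Each row is 1 of 27 tested gene lists, ordered by its permutation p for a joint shift; points are the 4 cultures, placed by the mean log2 deviation of the list's members from their own means. S phase and replication genes lie at -0.13 and -0.19 on replicates 1 and 3 and at 0.18 and 0.14 on replicates 2 and 4, and autophagy genes lie within 0.01 of 0.

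Of the 15 genes with the largest SD among those above the median level, 4 were set by a single array. Pkn2, a kinase gene, read 6.83 on replicate 2 and between -2.75 and -1.27 on the others, and its SD fell from 4.37 to 0.83 without replicate 2. Oser1 read 5.75 on replicate 2 and between 0.50 and 0.88 on the others, with an SD of 2.56, or 0.21 without replicate 2. Smim13 read 4.36 on replicate 4 and between -3.48 and -2.34 on the others, with an SD of 3.60, or 0.61 without replicate 4, and its other 2 named probes were not well above background on any array. Kmt2e, a chromatin regulator gene, read 2.97 on replicate 4 and between -0.83 and 0.60 on the others, with an SD of 1.57, or 0.81 without replicate 4. The spots around these probes on those arrays were raised too: 3 of 19 for Pkn2, 2 of 24 for Oser1, 5 of 24 for Smim13 and 6 of 24 for Kmt2e, where the mean over all spots was 0.0852 raised neighbours on replicate 2 and 0.117 on replicate 4. Within 6 rows in the same column, 6 of 12 spots were raised for Pkn2 and 4 of 12 for Oser1, those around Oser1 by 10.53 to 12.02 on the log2 scale.

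The other 11 genes of that set followed the pairs of cultures. Mitf, a transcription factor of the lysosomal and melanocyte programmes, read 3.60, 1.52, 3.57 and 1.71 on replicates 1 to 4. H1f4, a linker histone gene, read 1.04, 3.15, 1.13 and 3.36. Mdm4, a p53 regulator, read 0.80, -1.46, 0.84 and -1.71, and Ranbp2, a nuclear pore gene, read 0.08, -2.08, -0.03 and -2.05. Cavin2, a caveola component, read 2.82, 0.78, 2.90 and 0.76. The SDs of Akap9, Ro60, Rn5-8s, Hmgn5, Hipk3 and Arid3a were 1.51, 1.43, 1.40, 1.27, 1.15 and 1.14. All 3 Akap9 probes were detected on every array, with SDs from 1.11 to 1.51, whereas the 2 Hipk3 probes had SDs of 0.26 and 1.15.

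**Figure D4:**
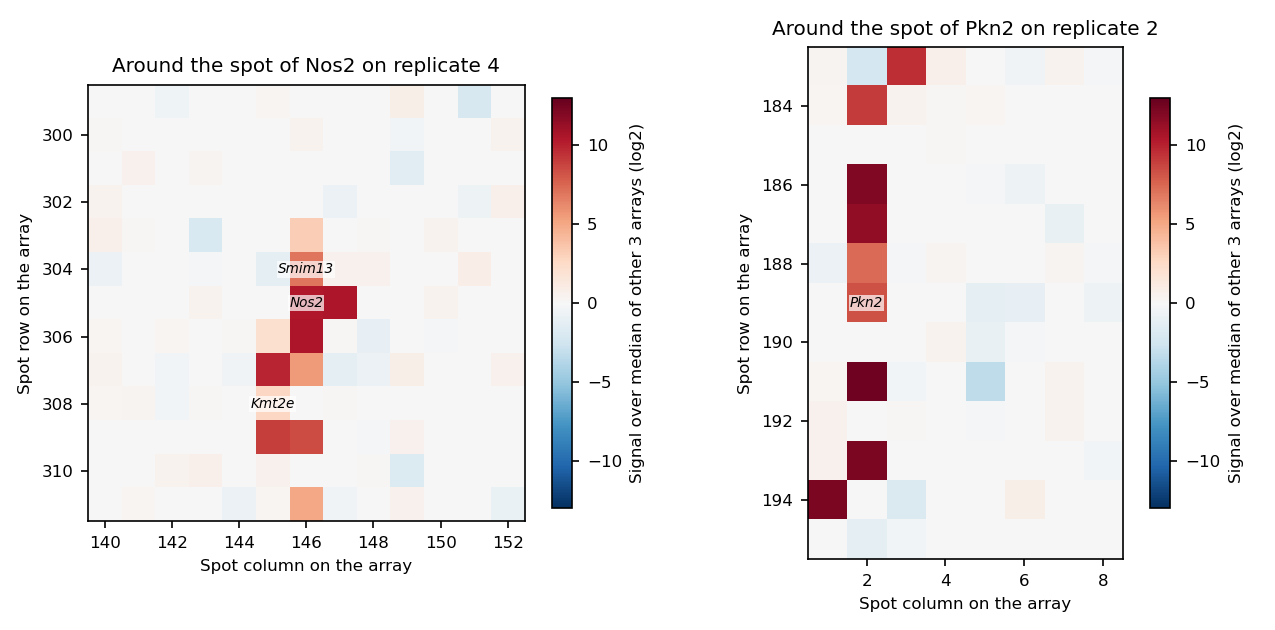
Colour shows each spot's log2 signal, floored at 50 units, over the median of the other 3 arrays, by its row and column on the array, around the spot of Nos2 on replicate 4 and of Pkn2 on replicate 2. Nos2, Smim13 and Kmt2e lie in 1 patch of raised spots, and Pkn2 lies in a column of raised spots.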

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

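Apart from the tests of gene lists, the tests of explanations in this part were chosen after the results they bear on had been seen. Of 109 values looked at for a sample far from the others, 7 had a gap to the nearest culture above Dixon's 95% critical value for 4 samples, as a share of the whole range. Chance alone would give about 5.45 if the values were independent and not picked by their spread. The flagged values of Pkn2, Smim13 and Oser1 belong to genes picked for the largest SD, and the arrays fell into pairs. The chance count therefore does not apply to these values as a set.

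Replicates 1 and 3, and replicates 2 and 4, resembled each other more than the rest, and a first component with scores of 0.50, -0.49, 0.50 and -0.51 on replicates 1 to 4 held 83.2% of the variance between arrays over the eligible genes, and 47.3% with no detection filter. Along this component the 7 detected spike-in probes spread 0.0855 times as widely as genes in the same level range. This argues against hybridisation or scanning that scatters probes of like level, but a spread does not show a movement that all 7 share. The unscaled signal at the 99th percentile was 66510 and 57020 on replicates 1 and 3, and 82820 and 93072 on replicates 2 and 4. Named genes detected numbered 9028 and 8845 on replicates 1 and 3, and 8641 and 8387 on replicates 2 and 4. Hybridisation or scanning is therefore not excluded. A trend with gene span and signal level took 14.7% of the variance along the first component. As fitted, span and level were therefore not the whole source. Transcript length and probe position in the transcript were not part of this trend, so their share stays open. The 1588 genes with the shortest spans deviated by a median of -0.14, 0.13, -0.13 and 0.14 on replicates 1 to 4. The design gives 1 group and so names no biological explanation, but gene lists were tested: 0 of 27 shifted together past the threshold, and S phase and replication genes, with mean deviations of -0.13, 0.18, -0.19 and 0.14 on replicates 1 to 4, had the smallest adjusted permutation p, 0.165, which ran from 0.0054 to 0.674 over the alternatives. Mitosis genes deviated by 0.04, -0.03, 0.02 and -0.03 (adjusted permutation p for a joint shift = 0.918), with members that went both ways. Among them Mki67 read 1.03, -0.53, 1.11 and -0.47, opposite in direction to the S phase deviations. Random lists were not matched on gene span, and the S phase deviations were close to those of the genes with the shortest spans. A difference in replication is therefore neither shown nor excluded. RNA quality, cultures handled in pairs, and repeat runs of 1 culture in each pair against the labels also stay open. So does an exchange of exposed and unexposed labels, for which 0 of 6 response lists shifted past the threshold decides nothing without unexposed arrays.

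The levels of Pkn2, Smim13 and Oser1 each had 1 culture far from the others, with gaps of 0.845, 0.854 and 0.927 of the range, on replicates 2, 4 and 2. Nos2 by its brighter probe, Smim13 and Kmt2e lay in 1 patch on replicate 4 with 8 other raised spots around them, where debris or a smear on the slide is a candidate source. The same is a candidate source for Pkn2 and Oser1 on replicate 2, which had 3 and 2 raised neighbours, because 6 and 4 of the 12 spots within 6 rows in their columns were raised, which 0.0270% and 0.110% of all spots there reached. For Kmt2e a raised transcript that both probes measure is argued against, because its second detected probe lay 0.11 over the lowest of the other arrays on replicate 4, where the first lay 3.80 over it. For Pkn2 and Oser1 no second named probe was at hand, the other Smim13 probes were not well above background, and the second Nos2 probe, above background on replicate 4 alone and outside the patch, lay 2.36 over the median of the other arrays there, so a raised transcript is not excluded for these genes.

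Il1b read 2.75 on replicate 2 and 2.58 to 2.60 on the others, a gap of 0.844 of the range. Ccl2 read 2.57 on replicate 2 and 2.45 to 2.47 on the others, a gap of 0.843 of the range. The residual of the spatial background fit was 12.01 intensity units on replicate 4 and 8.24 to 8.44 on the others, a gap of 0.948 of the range. Replicate 4 also had 1016 outlier spots against 623 to 675, a gap of 0.868 of the range.

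Signal also appeared in probes outside the gene comparisons. Of 96 ERCC control probes, ERCC-00148 was detected on all 4 arrays, with median signals of 91.8, 87.7, 59.8 and 112.1 on replicates 1 to 4, while the median of the other ERCC probes was between 8.56 and 12.1. A further 5776 probes with no gene symbol here were detected on all 4 arrays, 23.6% of the unnamed probes.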

How the results depend on the processing

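The first component share, the removal of genes in bright patches and the finer matching of random lists were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because all samples belong to 1 group. The count of genes detected on all arrays was 7944 and ran from 7082 with every probe of a gene required to 9875 with detection on any array; without 1 replicate it ran from 7965 to 8149. The median between-array SD rose from 0.234 to 0.350 with the array median and to 0.353 with the percentile over all non-control probes, and the cause was not tested; without 1 replicate it ran from 0.228 to 0.233. The lowest pairwise correlation was 0.967, and 0.953 with all non-control probes, which adds dim probes near background. The first component held 83.2% of the variance, 47.3% with no detection filter (cause not tested), and 80.2% to 86.4% under the other alternatives. For unusual spread, 0 lists were called, and 1 with quantile normalization (autophagy, narrower than random lists, adjusted permutation p = 0.0432; range over alternatives 0.0432 to 0.914). For a joint shift, 0 lists were called, and 1 with the median over members (S phase and replication, adjusted permutation p = 0.0054). Of 71 named genes, 69 changed level by more than their SD with the percentile over all non-control probes and 71 with the array median or quantile normalization, since these move the scale of all genes by a median of 3.37, 7.10 and 11.32; 15 did so with normexp and 13 with the mean over probes. Their SDs moved by over 1.5 times in 43, 36 and 34 genes under these settings, in 9 with normexp and in 5 with the mean over probes. Without replicates 1 to 4 in turn, SDs moved by over 1.5 times in 5, 7, 4 and 4 genes, 20 genes in all and each time downward. Without replicate 4, 8 levels moved by more than their SD. With the other detection flag, counts for 31 of 36 gene lists stayed within 1.5 times. Signal over background limits the dim genes: 6706 genes were not well above background, which does not show that they were not expressed.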

Other observations

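Gene families picked by symbol after the data were seen add to the description of the exposed cells. Of 12 toll-like receptor genes, Tlr2, Tlr4, Tlr6 and Tlr8 were detected on all 4 arrays and 7 on none. Of 17 cathepsin genes, which encode lysosomal proteases, 9 were detected on all arrays, and of 21 V-ATPase subunit genes, which acidify the lysosome, 16 were. Among 16 purinergic receptor genes, which sense extracellular nucleotides, 7 were, including P2rx4, P2ry2, P2ry6 and P2ry12. C-type lectin genes were detected for 12 of 30 members, among them Clec7a, the beta-glucan receptor, and the interleukin receptor genes for 12 of 32.

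Of 1106 olfactory receptor genes, 15 (1.36%) were detected on all 4 arrays, 155 on 1 to 3 arrays and 936 on none. Cytokeratin genes were detected for 2 of 47 members and beta-defensin genes for 1 of 37. Vomeronasal receptor genes were detected for 16 of 122 members (13.1%), above the share of olfactory receptors, and this difference was not tested.

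The pairing of cultures was seen by separate probes of most genes with 2 detected probes, but not of all. Over 1504 such genes, the scores of both probes on the first component had a Pearson r of 0.726 and a Spearman rho of 0.731. Genes are not independent replicates, and 77.7% of them had the same sign for both probes. Txnrd1 was an exception: its brighter probe read -0.94, -0.57, -0.96 and -0.52 on replicates 1 to 4, and its second probe -1.71, -2.28, -1.61 and -2.36. For Nlrp3 the brightest probe read -2.77, -2.32, -2.48 and -2.26, and another probe -4.28, -4.93, -4.28 and -4.88. Differences between the pairs in such genes depended on the probe. Across genes, the deviation from the gene's mean had a Spearman rho with gene span of 0.289 on replicate 1, -0.292 on replicate 2, 0.268 on replicate 3 and -0.259 on replicate 4. With signal level the Spearman rho was -0.283, 0.344, -0.276 and 0.229 on replicates 1 to 4. Spots raised at least 16-fold over the other arrays numbered 8, 35, 13 and 22 on replicates 1 to 4, and 0, 22, 10 and 12 of them had at least 3 raised neighbours. Of the eligible genes, 9 had a spot raised at least 4-fold with at least 3 raised neighbours.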
